A study of Drosophila melanogaster and Drosophila mauritiana and Drosophila simulans with 22 samples.

How the data were processed

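The series holds 22 arrays of testis RNA from 4 Drosophila species and 3 kinds of hybrid males with D. simulans mothers, with 4 arrays for D. mauritiana and 3 for each other group. Per the labels, 10 D. simulans females were crossed to 15 males per vial at 25 °C, and pools of 200 testes were taken from 4 day old males. The testis RNA was amplified in 1 round and labelled with Cy5, and total RNA of whole D. melanogaster males was labelled with Cy3 on every array, with no dye swap. Labelling and hybridisation were done at the Canadian Drosophila Microarray Centre. The deposited values are taken as log2 ratios of testes over whole flies: the order comes from the sample titles and goes with the low values of organ markers. The base of the deposited log2 values is inferred, not given in the sources used here. For deposited values between 3 and 8 in size, 2 was raised to that size and multiplied by 4. In the sechellia arrays 8.01, 12.5 and 12.6 percent of the products lay within 0.001 of a whole number, against at most 0.690 percent in any other array. Such ratios are a whole number or a whole number over 2 or 4. The within-array normalization is not given in the sources used here. No sample was left out, and the lowest correlation of any 2 arrays was -0.144.

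Of 27648 rows, 15116 carried 1 gene symbol in the probe table, 102 several, and 12430 were not listed. Rows with 1 symbol, 6793 genes, were used, and rows of the same gene were averaged per array. Symbols were matched as the table gives them, so a gene listed there under another symbol is missing from its list. Each array was centred on its median over the rows with gene names. A gene was tested with a value on at least 2 arrays of each of the 7 groups, which left 5107 genes. Arrays held 13019 to 27648 values, and the SD between duplicate spots was 0.22 to 0.48 outside sechellia.

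Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means, 1 estimate of the spread per gene from all 22 arrays) at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were the melanogaster arrays against 0, each pair of species, each hybrid against each parent and against the mean of its parents, the genes outside both parents, and their overlap between hybrids. Adjusted p-values in the text are those of limma. Errors are the SE of a difference or the SD between arrays, as marked. The comparisons, tests, filters, gene lists, rule for named genes and first alternatives were fixed before the data were examined. The named genes were, for each hybrid, the 6 furthest below and the 6 furthest above both parents whose arrays lay outside all parental arrays, and up to 3 members of each list with the smallest p. For species pairs they were the 4 highest and 4 lowest without overlap and up to 2 members of each list, and for melanogaster testes the 6 highest and 6 lowest and up to 3 of each list. Hybrid incompatibility genes, and genes outside both parents in all 3 hybrids, were named as well.

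There were 22 gene lists: spermatocyte transcription regulators (tTAF and tMAC), late spermatid, cup and comet, male meiosis, axonemal, Y-linked, testis-biased proteasome, germline stem cell and spermatogonial, piRNA pathway, testis somatic, hybrid incompatibility, accessory gland and duct, muscle, eye and nervous system, gut, fat body, blood cell, heat shock, antimicrobial and immune, cytoplasmic ribosomal, oxidative phosphorylation and general proteasome genes. The 13 lists with at least 5 tested genes were tested with camera of limma (preset correlation 0.01, and an estimated correlation as the alternative), 8 were described by gene, and the Y-linked list had no tested gene.

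The alternatives were no centring, 1 spread for all arrays, quantile normalization, genes on all arrays (3021) or on 1 array of each group (6510), 1 row per gene, the spread from the arrays compared, array weights, a 2-fold minimum, the replicate number as a block, and each array left out. Exact zeros treated as missing, a fit without sechellia, centring on the tested genes and averaging of the closest array pairs were added after seeing the data, and the splits of the arrays were then counted again with these pairs averaged. The fit was tested on simulated data: 5 draws of arrays with the noise of each group and no change, or with 200 changed genes. In the fit of all arrays it recovered between 42 and 65 percent of 4-fold changes in comparisons of groups, and 90.4 percent in melanogaster testes. Of 2-fold changes it recovered only 0.4 to 25.2 percent in comparisons of groups, and 19.2 percent in melanogaster testes. A planned test of X-linked genes was not run, since no chromosome table was used here.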

Results

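Testis expression was compared between Drosophila melanogaster, D. simulans, D. mauritiana and D. sechellia and 3 kinds of hybrid males with D. simulans mothers. The hybrids are named here by the father: the melanogaster hybrid, the mauritiana hybrid and the sechellia hybrid. Each of 22 arrays set amplified RNA of a pool of 200 testes of 4 day old males against RNA of whole D. melanogaster males, so every value is a log2 ratio of testes over the whole male fly. D. mauritiana had 4 arrays and each other group 3. Of 27648 rows, an array held between 13019 and 27648 values, and 5107 genes had values on at least 2 arrays of each group. The number of arrays limits the precision. The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure the spread between these samples. Arrays of melanogaster correlated at a median r of 0.82 across genes, which are not independent replicates, and those of simulans, mauritiana and the melanogaster hybrid at 0.81, 0.81 and 0.82. Mauritiana 2 correlated with mauritiana 1, 3 and 4 at only 0.73, 0.77 and 0.69, and with the melanogaster arrays at 0.72 to 0.79. Within these groups melanogaster 1 and 2 correlated at 0.94 and simulans 1 and 2 at 0.93. These pairs, and arrays 1 and 3 of the sechellia hybrid, differed by only 1.36, 1.12 and 1.37 times the noise of their spots, the lowest ratios within any group. They may thus be repeat runs of 1 RNA, which the labels do not say. If so, n is 2 in these 3 groups and p-values of comparisons with them are too small. Counts that moved with these close array pairs averaged are therefore given beside the main ones. The array pairs of the melanogaster hybrid had the next lowest ratios, 1.64, 1.63 and 1.69. They were not averaged, and whether they are repeat runs is not known either. The sechellia arrays correlated at only 0.31, and their duplicate spots differed with an SD of 1.30, 1.85 and 1.74, against 0.22 to 0.48 on every other array. In the sechellia hybrid, arrays 1 and 3 correlated at 0.82 and array 2 with them at 0.39 and 0.42.

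The melanogaster arrays compare testis with the whole body of the same species, which asks which genes the testis favours. Among post-meiotically transcribed genes, known as cup and comet genes, 6 of 6 rose in testis. They include soti (3.35 ± 0.35, SE), an inhibitor of a ubiquitin ligase in spermatids, and m-cup (2.16 ± 0.29). Of 8 late spermatid genes 5 rose and 0 fell in limma, among them Mst87F (2.52 ± 0.40), a sperm tail protein, and dj (2.08 ± 0.36), don juan. The list test of the late spermatid genes did not pass (median 1.25, adjusted p = 0.0966). Of 8 testis-biased proteasome genes 5 rose, with Prosbeta5R1 at 3.08 ± 0.33 and Rpt3R at 3.30 ± 0.45. The meiotic regulators rux (2.77 ± 0.32), mei-S332 (1.81 ± 0.33) and fwd (2.31 ± 0.33) and topi (2.53 ± 0.44), of the spermatocyte transcription complex tMAC, were also higher. Of 8 piRNA pathway genes 4 rose, such as vret (1.91 ± 0.27).

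All 5 accessory gland and duct markers fell in testis, such as Acp36DE (-4.76 ± 0.59), a seminal fluid protein of sperm storage. So did 8 of 10 gut markers, with the digestive protease Jon99Fii at -5.10 ± 0.30, and 5 of 7 muscle markers, with Mlc2 at -3.77 ± 0.40. Of the other gut markers 1 rose and 1 did not pass. Of 7 eye and nervous system markers 3 fell, with the photoreceptor arrestin Arr2 at -5.69 ± 0.67. Of 6 heat shock genes 4 fell, with Hsp68 at -3.44 ± 0.36. Among 20 ribosomal protein genes 7 fell and 5 rose, and among 34 oxidative phosphorylation genes 15 fell and 10 rose. Among the latter COX6CL (3.88 ± 0.41) and COX6AL (3.05 ± 0.33), paralogs of cytochrome oxidase subunits, rose and Cyt-c1 (-3.08 ± 0.43) fell. The highest ratios were those of CG4892 (4.48 ± 0.43) and CG13021 (4.40 ± 0.55), the lowest those of CG12374 (-6.30 ± 0.48) and CG16826 (-6.25 ± 0.50). In all, 1550 of 5107 genes were higher and 710 lower in testis (n = 3 arrays, limma). Centred on the tested genes the split was 1318 higher and 980 lower, and with close array pairs averaged 1090 and 424.

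In the list tests of limma, gut markers (adjusted p = 6.68e-12), accessory gland markers (1.41e-05) and eye markers (0.00542) lay lower and kept that call with an estimated correlation (1.73e-05, 0.00382 and 0.0348). Cup and comet genes and testis proteasome genes lay higher (adjusted p = 0.0116 and 0.0152), with adjusted p = 0.102 and 0.185 with an estimated correlation. Muscle markers (median -1.80), heat shock genes (-1.28) and ribosomal protein genes (-0.75) lay lower at adjusted p = 0.00303, 0.0116 and 0.0152. With an estimated correlation these became adjusted p = 0.102, 0.102 and 0.19. Adjusted over the list alone, 6 testis proteasome genes were higher and 6 muscle and 4 eye markers lower. All arrays had the same dye order, so a dye bias of a gene adds to these ratios but cancels between groups. Only the testis RNA was amplified, so an amplification bias of a gene adds to these ratios as well. The test against 0 also leaves out the spread of the whole-male reference.

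Between simulans and melanogaster, the most similar pair by correlation (median r = 0.77), most calls were of genes lower in simulans. Weaker binding of RNA of another species to probes of melanogaster sequence would also lower values against melanogaster, here and in mauritiana and sechellia. It was not tested for the species pairs and cannot be told apart from lower expression. The calls were 54 genes, 2 higher and 52 lower (limma, n = 3 arrays per species), and with close array pairs averaged 1 gene, Ufsp2. CG31909 fell by 3.70 ± 0.71 (SE), Dpy-30L2 was at -3.70 ± 0.72 and Ufsp2, a protease that processes a ubiquitin-like protein, at -3.06 ± 0.35. The comet gene schuy fell by 2.73 ± 0.52, while DopEcR, a receptor for dopamine and ecdysteroids, rose by 2.53 ± 0.57. Cup and comet genes lay lower as a list (median -0.74, adjusted p = 0.00942, and adjusted p = 0.199 with an estimated correlation), with 1 of 6 past the threshold. The accessory gland list lay higher (median 0.82, adjusted p = 0.0245, and adjusted p = 0.232 with an estimated correlation), but its test turned downward when the arrays were scaled to 1 spread. Of these markers 0 passed over all genes and 1 adjusted over the list alone. With the spread taken from these 6 arrays alone 925 genes passed, 214 higher and 711 lower, which include all 54. On simulated arrays this fit recovered 43 percent of 2-fold and 97.6 percent of 4-fold changes, against 0.4 and 46.8 percent in the fit of all arrays. The 54 calls are thus no measure of how few genes differ. Without melanogaster 1 or 2 the count was 18 or 15, and without simulans 1 or 3 it was 32 or 8. With those arrays left out, or with the closest array pairs averaged, the calls of schuy, Dpy-30L2, CG31909 and DopEcR ended in at least 1 fit, and that of Ufsp2 in none.

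D. mauritiana differed from melanogaster at 339 genes, 112 higher and 227 lower, and from simulans at 563 genes, 344 higher and 219 lower (limma, n = 4 against 3 arrays). With close array pairs averaged these counts fell to 50 (18 higher, 32 lower) and 97 (76 higher, 21 lower). Against melanogaster, pim, the fly securin, fell by 3.67 ± 0.38 (SE), and polybromo, a subunit of a chromatin remodelling complex, was at -3.05 ± 0.36. The piRNA factor vret fell by 2.10 ± 0.35, while CG5539 rose by 4.00 ± 0.49 and the mitochondrial ribosomal protein gene mRpS34 by 3.04 ± 0.42. Against simulans, schuy rose by 4.39 ± 0.49, CG8746 by 3.80 ± 0.66 and POLDIP2 by 3.64 ± 0.44, while CG31451 fell by 3.49 ± 0.55. S-Lap5, a leucyl aminopeptidase of sperm, was higher than in simulans (2.71 ± 0.44) and than in melanogaster (2.18 ± 0.44). ND-B18, a subunit of respiratory complex I, was lower in both comparisons (-2.37 ± 0.43 and -2.19 ± 0.43). The mitochondrial chaperone Hsc70-5 was higher than in simulans (2.13 ± 0.45). Accessory gland markers were higher than in melanogaster, with 3 of 5 past the threshold, also 3 adjusted over the list alone, and Acp53Ea at 2.48 ± 0.47. Their list had a median of 2.48 (adjusted p = 0.000461, and adjusted p = 0.0351 with an estimated correlation). This averaging ended the calls of S-Lap5 and ND-B18 against melanogaster.

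Heat shock genes were higher than in melanogaster by a median of 1.23 (adjusted p = 0.00163), with 3 of 6 members past the threshold and adjusted p = 0.0583 with an estimated correlation. Against simulans their median was 0.92 (adjusted p = 0.0363, and adjusted p = 0.425 with an estimated correlation). Late spermatid genes had medians of 0.57 and 0.61 against melanogaster and simulans, the latter -0.07 with scaled arrays and -0.01 after quantile normalization. Their adjusted p = 0.0033 and 0.0363 became adjusted p = 0.26 and 0.425 with an estimated correlation. The median of this list on mauritiana array 2 was 1.29, within the melanogaster arrays (1.06 to 1.49). On mauritiana arrays 1, 3 and 4 it was 2.33, 2.50 and 2.70. Oxidative phosphorylation genes lay lower than in melanogaster (median -0.72, adjusted p = 0.00376, and adjusted p = 0.585 with an estimated correlation). The medians of this list per array ranged from -1.58 to -0.22 in mauritiana and from -0.85 to -0.60 in melanogaster. The highest mauritiana array thus lay above every melanogaster array. With the spread from the arrays compared alone, 623 genes differed from melanogaster and 1008 from simulans. The melanogaster comparison gave 90, 86 and 184 genes without melanogaster 1, 2 and 3, and 143 and 129 without mauritiana 1 and 3. The simulans comparison gave 194, 191 and 252 genes without simulans 1, 2 and 3, and 287 and 331 without mauritiana 3 and 4. Without mauritiana 2 the counts rose, to 499 against melanogaster (225 higher, 274 lower) and 765 against simulans (473 higher, 292 lower). With scaled arrays the simulans comparison had 373 genes higher and 609 lower, and after quantile normalization 477 and 717. Centred on the tested genes, the melanogaster comparison had 180 higher and 178 lower.

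With the spread from all arrays the sechellia pairs gave more calls than the other species pairs, an order that did not hold with the spread from the arrays compared, with array weights, or, for mauritiana against sechellia, with scaled arrays and after quantile normalization. The calls were 1722 genes against melanogaster (391 higher, 1331 lower), 1339 against simulans (345 and 994) and 1166 for mauritiana against sechellia (841 and 325). With close array pairs averaged they were 1021, 521 and 883. The comet gene soti was lower in sechellia than in melanogaster (-5.67 ± 0.49, SE) and simulans (-5.10 ± 0.49), and higher in mauritiana than in sechellia (3.55 ± 0.46). Prosbeta4R2 was lower than in melanogaster (-3.66 ± 0.55) and higher in mauritiana than in sechellia (2.53 ± 0.52). Hsp68, a stress-induced chaperone, was higher than in melanogaster (3.32 ± 0.51) and simulans (2.61 ± 0.51). CG9825 was higher (6.74 ± 0.75 and 5.30 ± 0.75), as was spict (5.29 ± 0.50 and 5.50 ± 0.50), and CG32267 was lower (-6.99 ± 0.76 and -5.58 ± 0.76). Art9, an arginine methyltransferase, was higher than in simulans (5.22 ± 0.39), and lower in mauritiana than in sechellia (-5.81 ± 0.43). Of 34 oxidative phosphorylation genes 20 fell against melanogaster, with ATPsynE at -4.11 ± 0.53 and ATPsynB at -3.70 ± 0.48, and 18 against simulans. Their list medians were -1.70 and -1.32 (adjusted p = 0.00423 and 0.00435), with adjusted p = 0.703 and 0.902 with an estimated correlation, and both calls also ended with scaled arrays and after quantile normalization. Of 20 ribosomal protein genes 11 fell against melanogaster, with RpL24-like at -3.43 ± 0.56.

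The median of all tested genes itself lay at -0.48 against melanogaster and -0.36 against simulans, and the lists above are tested against all other genes. In a fit of the arrays compared alone, 726 genes differed from melanogaster, 329 from simulans and 169 between mauritiana and sechellia, fewer than the 925 of simulans against melanogaster and the 1008 of mauritiana against simulans. Of these, 720, 327 and 169 were shared with the calls above in the same direction. On simulated arrays with no difference, the fit of all arrays still called 96, 71.8 and 214.6 genes on average in these 3 comparisons. The fit of the arrays alone called 0 there, and it recovered 0% of simulated 4-fold changes. Without centring, the splits of higher and lower were 453 and 835, 397 and 504, and 494 and 386. Centred on the tested genes they were 623 and 955, 463 and 815, and 717 and 445. The simulans comparison gave 709 and 696 genes without simulans 1 and 2, and mauritiana against sechellia 745 without mauritiana 4.

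**Figure D1:**
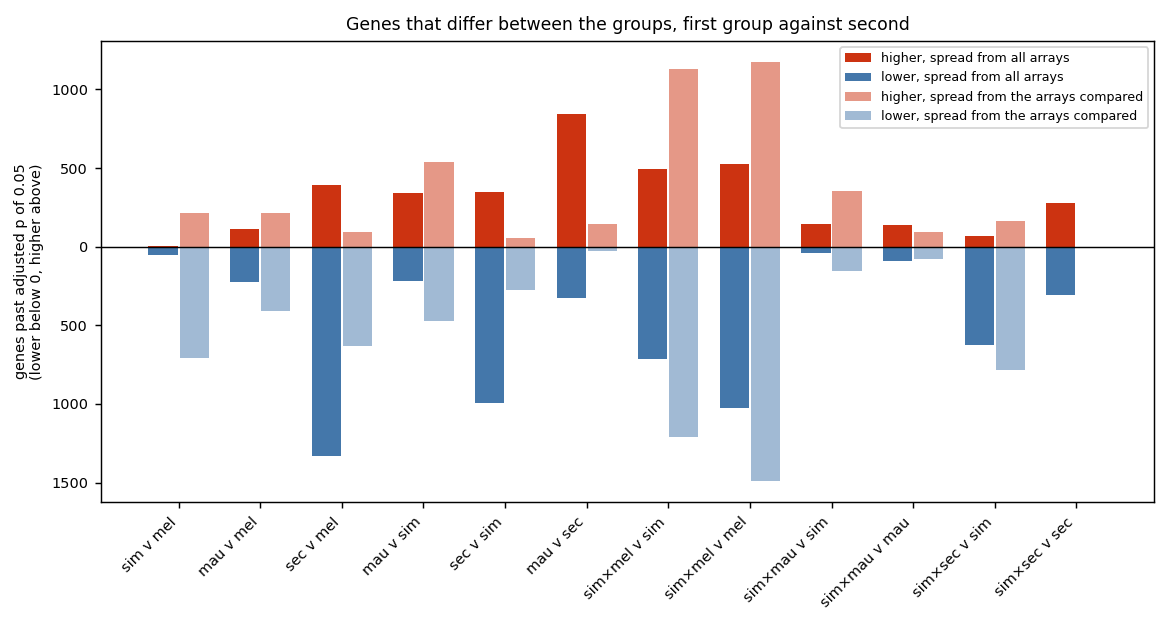
Bars give the number of genes past an adjusted p of 0.05 (limma), higher in the first group above 0 and lower below 0, for each pair of groups with the hybrids named by mother and father. Dark bars take the spread of each gene from all 22 arrays and pale bars from the arrays compared, where the sechellia hybrid against sechellia drops from 583 genes to 0.

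The melanogaster hybrid stood furthest from its parents, with array correlations of 0.17 (median) to simulans and 0.15 to melanogaster. Late germline genes fell. All 8 late spermatid genes were lower than the mean of the parents, with a median of -3.35. The don juan gene dj, whose product lies in sperm, was at -3.37 ± 0.47 (SD, n = 3) in the hybrid, 1.80 ± 0.65 (SD, n = 3) in simulans and 2.08 ± 0.24 (SD, n = 3) in melanogaster. Mst87F fell by 5.62 ± 0.49 (SE) and ocn was at -3.92 ± 0.39. Of 6 cup and comet genes 5 fell, with soti at -5.59 ± 0.43, m-cup at -3.74 ± 0.35 and boly at -3.12 ± 0.45. Of 8 testis-biased proteasome genes 6 fell, with Prosbeta4R2 at -4.27 ± 0.48, Prosbeta5R1 at -3.95 ± 0.41 and Prosbeta2R1 at -2.05 ± 0.31. Among meiosis genes 5 of 9 fell, with mei-S332, which protects sister chromatid cohesion, at -3.30 ± 0.41, rux at -2.48 ± 0.39 and fwd at -2.44 ± 0.40. The testis tubulin betaTub85D, alone of 4 axonemal genes, fell by 4.53 ± 0.54. Alone of 4 spermatocyte transcription regulators topi passed as lower, at -2.55 ± 0.53. The median of these 4 genes on the hybrid arrays (-0.05 to 0.22) nevertheless lay below that on every parental array (1.46 to 1.94).

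The piRNA pathway list shifted less than the late lists: against the lower parent it lay at -0.58, late spermatid genes at -3.47 and cup and comet genes at -2.62. Of 8 piRNA pathway genes 2 fell, vret (-1.44 ± 0.33) and mael (-0.88 ± 0.31), and the list did not pass (median -0.81, adjusted p = 0.341). Its median on the hybrid arrays (-0.15 to 0.17) still lay below that on every parental array (0.43 to 0.92). The call of mael ended with close array pairs averaged and in 7 of the 9 fits that left out 1 array (without melanogaster 1 or 2, simulans 1 or 3, or any hybrid array). Of 3 germline stem cell and spermatogonial genes none passed in limma, with bam, the switch to differentiation, at 0.86 ± 0.54 and Rbfox1 at 0.79 ± 0.32. Both passed, as higher, with the spread from the arrays compared and with array weights, and Rbfox1 also with scaled arrays, after quantile normalization, without the sechellia arrays and centred on the tested genes. Of 34 oxidative phosphorylation genes 11 fell and 1 rose, with the lowest values among the named ones for COX7AL (-4.93 ± 0.52), COX6CL (-4.37 ± 0.50) and ATPsynGL (-3.29 ± 0.40), paralogs named as like the standard subunits. Of 20 general proteasome genes 5 fell, among them Rpn2 (-1.67 ± 0.42), and 1 rose. Neither list passed as a whole (adjusted p = 0.117 and 0.734).

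In the melanogaster hybrid all 5 accessory gland and duct markers were above the mean of the parents: Acp53C14a by 7.19 ± 0.63, Acp53Ea by 5.77 ± 0.44 and Acp36DE by 3.66 ± 0.73. Acp36DE was at -0.68 ± 0.24 (SD, n = 3) in the hybrid, -3.94 ± 0.42 (SD, n = 3) in simulans and -4.76 ± 0.63 (SD, n = 3) in melanogaster. Of 20 ribosomal protein genes 12 rose and 1 fell, with RpL17 at 3.64 ± 0.37, RpL27 at 2.71 ± 0.46 and RpS28b at 2.22 ± 0.35. Of 3 blood cell markers 2 rose: crq, a phagocytic receptor, by 2.53 ± 0.50 and Pxn, a peroxidase of the extracellular matrix, by 1.46 ± 0.40. The call of Pxn ended with 1 row per gene. Of 3 fat body markers 1 rose, the lipoprotein gene apolpp (1.27 ± 0.30), with a list median of -0.05. Of 10 gut markers 1 rose, the protease gene Jon66Cii (1.90 ± 0.37), and the gut list did not pass (median 0.25, adjusted p = 0.341). Of 7 eye and nervous system markers 2 rose, among them the photoreceptor channel gene trpl (1.37 ± 0.29). Of 7 muscle markers 2 fell, Act88F, flight muscle actin (-2.14 ± 0.55), and Act79B (-2.72 ± 0.72), with 3 lower adjusted over the list alone, and the muscle list did not pass (median -1.34, adjusted p = 0.341). As a list eye markers had a median of -0.14 but a mean of 0.21, with a test toward higher (adjusted p = 0.409).

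**Figure D2:**
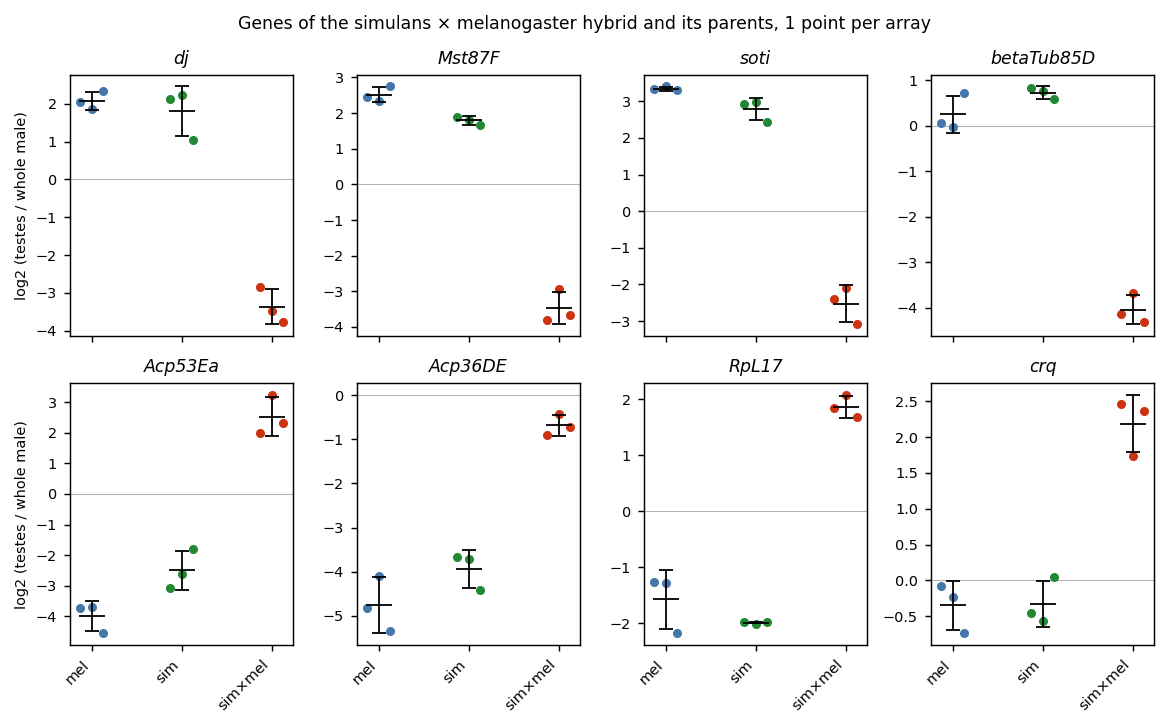
Points give the log2 ratio of testes over whole male flies on each array for 8 genes in melanogaster (mel), simulans (sim) and their hybrid (sim×mel), with the mean and SD as bars. The hybrid arrays lie below all parental arrays for dj, Mst87F, soti and betaTub85D and above them for Acp53Ea, Acp36DE, RpL17 and crq, with dj at a mean of -5.31 against the mean of the parents.

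Counted against each parent, 1207 genes differed from simulans (495 higher, 712 lower) and 1552 from melanogaster (526 higher, 1026 lower; limma, n = 3 arrays per group). Past the threshold against both parents lay 666 genes below and 358 above. The most extreme below both were CG8517 (-7.14 ± 0.56 against simulans, SE), CG4218 (-7.11 ± 0.54), CG17470 (-7.15 ± 0.56) and CG17377 (-6.58 ± 0.50), with scpr-C, a member of a cysteine-rich secretory family, at -7.02 ± 0.54. Above both were Acp53C14a (7.01 ± 0.73), CG4250 (5.02 ± 0.39), CG15096 (4.88 ± 0.84), NtR (4.38 ± 0.54) and CG16926 (4.26 ± 0.44). Against the mean of the parents, the late spermatid (3.2e-08), cup and comet (2.48e-05), testis proteasome (0.000183), accessory gland (2.51e-06) and ribosomal (0.000183) lists passed in limma at these adjusted p. With an estimated correlation they passed at adjusted p = 0.00492, 0.00492, 0.0364, 0.003 and 0.043. The meiosis list (median -0.81) passed at adjusted p = 0.036 and lost its call with an estimated correlation (adjusted p = 0.111). Adjusted over the list alone, 8 late spermatid, 6 cup and comet, 7 testis proteasome, 5 meiosis and 5 piRNA genes were lower, and 5 gland and 13 ribosomal genes higher.

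With the spread from the 9 arrays alone, 1082 genes lay below and 865 above both parents, and 1024 of these were shared with the calls of all arrays. Without hybrid array 3, 232 genes lay above both parents, and with close array pairs averaged 237 above and 474 below. Without centring 282 genes were higher and 762 lower than simulans, and 279 and 1101 than melanogaster. After quantile normalization the split was 984 higher and 970 lower against simulans, and 973 and 1116 against melanogaster. Outside both parents 846 genes then lay below and 707 above.

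**Figure D3:**
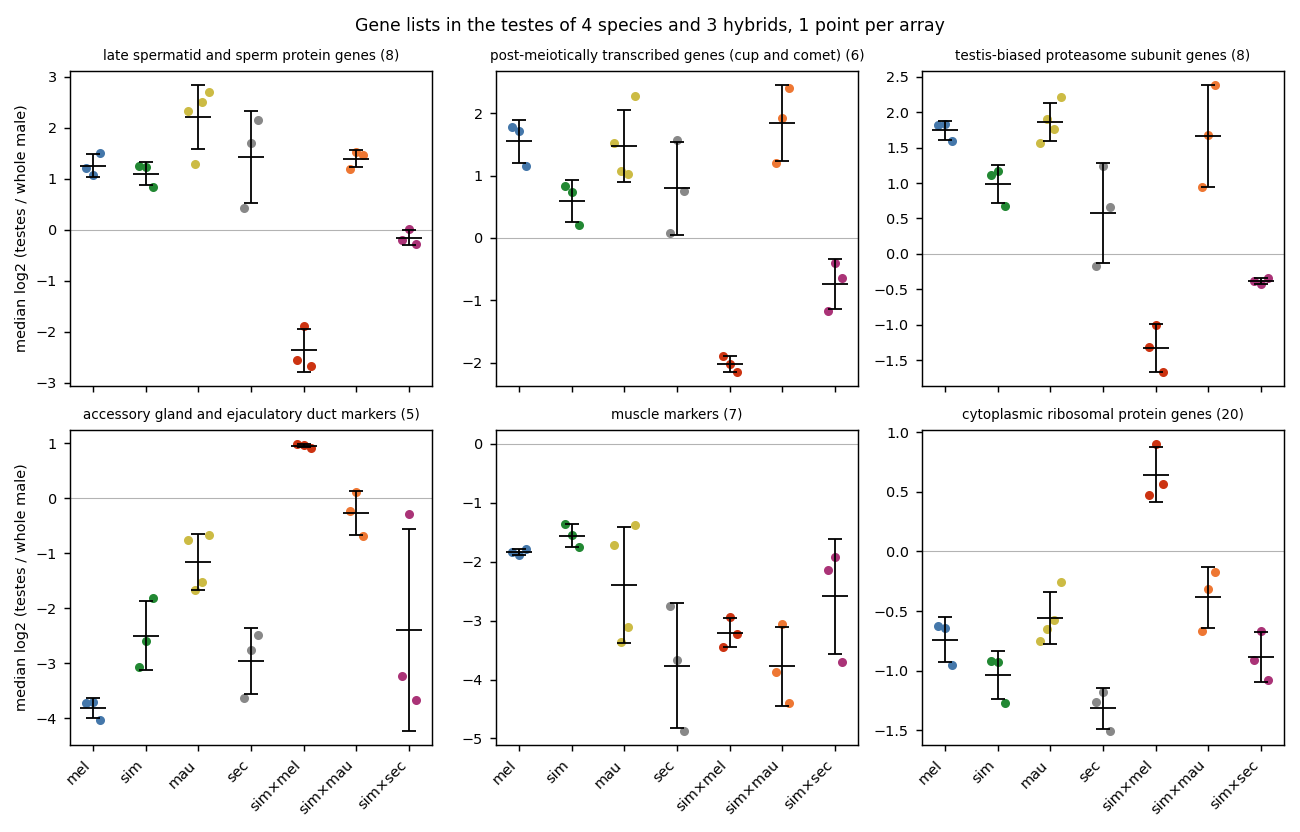
Each point is the median log2 ratio of testes over whole male flies of a gene list on 1 array, with the mean and SD of each group as bars; the number of genes follows each list's name. The melanogaster hybrid (sim×mel) lies lowest for late spermatid genes at -2.37 ± 0.43 and highest for accessory gland markers at 0.96 ± 0.03 (SD, n = 3), beside -1.15 ± 0.51 in mauritiana (SD, n = 4).

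In the mauritiana hybrid few genes lay outside both parents, and its late spermatid list did not pass (median -0.04 against the mean of the parents, adjusted p = 0.609). Spase22-23, a signal peptidase subunit, rose by 3.61 ± 0.55 (SE) against simulans and 2.80 ± 0.51 against mauritiana. Tmem43, a membrane protein gene, rose by 2.51 ± 0.46 and 1.99 ± 0.43, CG10570 by 2.18 ± 0.50 and 3.81 ± 0.47, and HP1c, a heterochromatin protein 1 paralog, by 1.96 ± 0.50 and 2.36 ± 0.47. The cup gene p-cup rose by 2.04 ± 0.46 and 2.48 ± 0.43. Below both parents were CG1835 (-2.75 ± 0.62 and -2.67 ± 0.58), CG14488 (-1.98 ± 0.51 and -1.97 ± 0.47) and CG15333 (-1.18 ± 0.32 and -1.86 ± 0.30). Of 5 accessory gland markers 1 rose against the mean of the parents, Acp53Ea by 2.11 ± 0.43, and 3 rose adjusted over the list alone. Their list had a median of 1.70 (limma, adjusted p = 0.00115, and adjusted p = 0.0847 with an estimated correlation). Of 7 muscle markers 0 fell over all genes and 4 adjusted over the list alone, with a median of -1.52 (adjusted p = 0.000397, and adjusted p = 0.0884 with an estimated correlation). The ribosomal protein gene RpS10a rose by 1.65 ± 0.29.

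From simulans 184 genes differed (141 higher, 43 lower) and from mauritiana 230 (140 higher, 90 lower), with 36 above and 3 below both (limma, n = 3 or 4 arrays). With close array pairs averaged these counts fell to 7, 131, 2 and 0. Spase22-23 kept its calls against both parents in every fit run, and of the others named above each lost 1 or more when a simulans array or hybrid array 1, 2 or 3 was left out, and all of these but RpS10a lost 1 with close array pairs averaged. The simulans comparison gave 39, 37 and 13 genes without simulans 1, 2 and 3, and 283, 69 and 12 without hybrid 1, 2 and 3. The mauritiana comparison gave 136 and 130 genes without mauritiana 1 and 3, and 101 and 105 without hybrid 2 and 3. The 36 above both became 6, 8 and 3 without simulans 1, 2 and 3, 23 without mauritiana 1, and 71, 12 and 1 without hybrid 1, 2 and 3. The 3 below both became 0 without any 1 simulans array or without hybrid 3, and 5 without mauritiana 2. With the spread from the arrays compared, 513 and 171 genes passed, and 60 above and 8 below both. Without centring 60 genes were higher and 53 lower than simulans, and 52 and 134 than mauritiana. With scaled arrays 298 were higher and 294 lower than simulans, and after quantile normalization 351 and 338. Centred on the tested genes the splits were 146 and 75 against simulans and 138 and 138 against mauritiana.

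In the sechellia hybrid some members of the late germline and proteasome lists fell, while none of these lists held its call with an estimated correlation and the members named here lost theirs with the spread from the arrays compared. Of 6 cup and comet genes 2 fell against the mean of the parents, soti (-1.99 ± 0.43, SE) and schuy (-1.94 ± 0.45) among them. Of 8 late spermatid genes 3 fell, such as dj (-1.68 ± 0.44), and 5 fell adjusted over the list alone. Of 20 general proteasome genes 4 fell, such as Prosalpha7 (-1.92 ± 0.47), and 8 adjusted over the list alone. Of 8 testis-biased proteasome genes 2 fell, such as Rpt3R (-2.01 ± 0.55), and 5 adjusted over the list alone. The cohesion protector mei-S332 fell by 1.92 ± 0.41 and ATPsynB, a subunit of the mitochondrial ATP synthase, was at -2.03 ± 0.43. Below both parents were CG18130 (-3.17 ± 0.55 against simulans), CG18568 (-2.83 ± 0.52), CG3213 (-2.58 ± 0.52) and Sfxn1-3 (-2.71 ± 0.52), a mitochondrial carrier, and above both was CG5853 (2.05 ± 0.50). Late spermatid (median -1.45), cup and comet (-0.98), testis proteasome (-1.08) and general proteasome (-0.92) lists passed at adjusted p = 0.00203, 0.0248, 0.00378 and 0.00314. With an estimated correlation these became adjusted p = 0.227, 0.241, 0.227 and 0.614. Accessory gland markers did not pass (median 0.42, adjusted p = 0.338), with array 2 at -0.28 and arrays 1 and 3 at -3.23 and -3.67.

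From simulans 697 genes differed (69 higher, 628 lower), and from sechellia 583 (276 higher, 307 lower), with 64 below and 5 above both (limma, n = 3 arrays per group). With the spread from the arrays compared, 947 genes differed from simulans and 0 from sechellia, so 0 lay outside both. At an unadjusted p under 0.05, 1428 genes differed from sechellia in the fit of all arrays. That fit called 186.2 genes on average in simulated arrays with no difference between this hybrid and sechellia. The named genes lost their calls against the mean of the parents or sechellia in the fit of the arrays compared and when the closest array pairs, hybrid 1 and 3 among them, were averaged, which left 59 genes against simulans and 51 against sechellia. Leaving out simulans 1 or 2, sechellia 2 or 3, or any hybrid array ended the call of at least 1 of dj, schuy, Rpt3R, Prosalpha7, mei-S332, ATPsynB and CG5853. The simulans comparison gave 244 and 266 genes without simulans 1 and 2, and 447 without hybrid 1. The sechellia comparison gave 1609, 326 and 305 genes without sechellia 1, 2 and 3, and 140 and 209 without hybrid 1 and 3. The 64 below both became 27 without simulans 1 or 2, 205, 27 and 24 without sechellia 1, 2 and 3, and 13, 144 and 16 without hybrid 1, 2 and 3. The 5 above both became 0 without any 1 simulans array, 49 and 9 without sechellia 1 and 2, and 1, 9 and 19 without hybrid 1, 2 and 3. With scaled arrays 287 genes were higher and 1078 lower than simulans, after quantile normalization 526 and 960, and without centring 52 were higher and 652 lower than sechellia. Outside both parents 89 lay below and 28 above with scaled arrays, 83 and 76 after quantile normalization, and 218 and 0 without centring.

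Of the 54 genes called between simulans and melanogaster, the melanogaster hybrid differed from melanogaster only at 35, from simulans only at 2, from both at 15 and from neither at 2. This set shrank to between 8 and 48 genes with 1 array left out and to 1 with close array pairs averaged, so these classes do not show which parent the hybrid resembles. In the mauritiana hybrid 379 of 563 differed from neither parent, 91 from simulans only, 90 from mauritiana only and 3 from both. In the sechellia hybrid 547 of 1339 differed from neither, 446 from simulans only, 330 from sechellia only and 16 from both. A gene past the threshold against 1 parent only is not shown to differ between the parents in its distance to the hybrid, which was not tested. Where the parents were not told apart, the melanogaster, mauritiana and sechellia hybrids differed from both at 1009 of 5053, 36 of 4544 and 63 of 3768 genes. Most tested genes are of this kind, so these counts do not show that departures gather where the parents agree. CG15333 alone was below both parents in all 3 hybrids (-1.68 ± 0.32, -1.18 ± 0.32 and -1.47 ± 0.32 against simulans, SE), and its calls in the mauritiana and sechellia hybrids ended with close array pairs averaged, the former also without any 1 simulans array and without mauritiana hybrid 2 or 3. The melanogaster and sechellia hybrids shared 55 genes below both parents, of 666 and 64, against 8.35 for independent lists, and 1 above, CG5853. Both this overlap and the sechellia hybrid's genes outside both parents became 0 with close array pairs averaged, and with the spread from the arrays compared 0 sechellia hybrid genes lay outside both parents (limma). The melanogaster and mauritiana hybrids shared CG14488 and CG15333 below, where 0.391 were expected of independent lists, and CG10570 and Spase22-23 above, where 2.52 were. The mauritiana and sechellia hybrids shared CG15333 alone, where 0.0376 were expected below. In 100 simulations with no effect the shared counts were 0, but these called 0 genes outside both parents in any hybrid, so they do not show what the shared simulans arrays add. All 3 hybrids are compared with the same 3 simulans arrays, which cannot be split into groups of 2, so part of the excess may come from those arrays. The 4 genes that the melanogaster and mauritiana hybrids shared became 1 without any 1 simulans array or with close array pairs averaged, 7 without mauritiana 2, and 11, 1 and 1 without mauritiana hybrid 1, 2 and 3. The 56 genes that the melanogaster and sechellia hybrids shared became 22, 22 and 35 without simulans 1, 2 and 3, 169, 24 and 22 without sechellia 1, 2 and 3, and 12, 90 and 18 without sechellia hybrid 1, 2 and 3.

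The tested genes known for hybrid incompatibility, Hmr, Lhr and agt, showed no departure from the parents' mean past the threshold in limma with the spread from all arrays. Hmr, linked to lethality of hybrids between melanogaster and simulans, was at 0.16 ± 0.24 (SD, n = 3) in that hybrid, -0.60 ± 0.16 (SD, n = 3) in melanogaster and -0.23 ± 0.17 (SD, n = 3) in simulans. Its partner Lhr was at -0.15 ± 0.51, 0.71 ± 0.16 and 0.27 ± 0.55 (SD, n = 3). The differences from the mean of the parents were 0.57 ± 0.29 (SE, adjusted p = 0.156) for Hmr and -0.64 ± 0.35 (adjusted p = 0.182) for Lhr. Hmr passed, as higher, with the spread from the arrays compared and with array weights, with which Lhr also passed as lower in this hybrid and as higher in the mauritiana hybrid, and agt as lower there. OdsH, linked to male sterility between simulans and mauritiana, was not tested for lack of values and was at -0.34 ± 0.50 (SD, n = 2) in the mauritiana hybrid and 0.11 ± 0.27 (SD, n = 3) in simulans. Nup160 was at -0.35 ± 0.34 (SD, n = 3) in the melanogaster hybrid. There gfzf was at 0.48 ± 0.10 (SD, n = 3), below both parents, with 2.74 ± 0.04 in melanogaster and 1.02 ± 0.15 in simulans. Neither gene was tested, since each had a value on only 1 array of the sechellia hybrid. The gene agt differed between species, lower in mauritiana than in simulans (-1.50 ± 0.46, adjusted p = 0.042), a call that ended with close array pairs averaged and in 6 of 7 fits without 1 array, all but mauritiana 2.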

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

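The tests of ratios drawn toward 0, of late germ cells, of probe mismatch and of the preparation of the sechellia arrays, the comparison between hybrids and that of unlisted rows were chosen only after the results were seen. The departure of each hybrid from the mean of its parents was compared between hybrids, as a test of the difference itself (limma). It differed between the melanogaster and mauritiana hybrids at 1174 genes (285 higher and 889 lower in the melanogaster hybrid), between the melanogaster and sechellia hybrids at 743 (305 and 438), and between the mauritiana and sechellia hybrids at 230 (205 and 25). No other fit and no simulation was run for these 3 counts. The noisy sechellia arrays enter the last 2, and the same fit called 186.2 genes on average between the sechellia hybrid and sechellia in simulated arrays with no difference. Late spermatid genes departed by -3.91 more in the melanogaster than in the mauritiana hybrid (median of 8 genes, 8 lower, adjusted p = 4.93e-07, and adjusted p = 0.0137 with an estimated correlation). Cup and comet genes departed by -3.36 (5 of 6 lower, adjusted p = 3.19e-06, and adjusted p = 0.004 with an estimated correlation) and testis proteasome genes by -2.86 (6 of 8 lower, adjusted p = 0.000126, and adjusted p = 0.0348 with an estimated correlation). Accessory gland markers departed by 2.20 (2 of 5 higher, adjusted p = 0.00229, and adjusted p = 0.0455 with an estimated correlation), and against the sechellia hybrid by 3.25 (3 of 5 higher, adjusted p = 2.95e-06, and adjusted p = 0.00225 with an estimated correlation). Other lists passed and lost their call with an estimated correlation. Between the melanogaster and mauritiana hybrids these were meiosis genes (-1.29, 5 of 9 lower, adjusted p = 0.0193, and adjusted p = 0.0866 with an estimated correlation) and ribosomal protein genes (1.13, 5 of 20 higher and 2 lower, adjusted p = 0.00892, then 0.168). Between the melanogaster and sechellia hybrids they were late spermatid (-2.18, 5 of 8 lower, adjusted p = 2.57e-05, and adjusted p = 0.0504 with an estimated correlation), cup and comet (-1.30, 3 of 6 lower, 0.00141, then 0.0504), testis proteasome (-0.98, 2 of 8 lower, 0.0269, then 0.271) and ribosomal protein genes (1.14, 4 of 20 higher and 1 lower, 0.0012, then 0.092). Between the mauritiana and sechellia hybrids they were late spermatid (1.34, 1 of 8 higher, adjusted p = 0.0238, and adjusted p = 0.373 with an estimated correlation), cup and comet (1.79, 2 of 6 higher, 0.00721, then 0.275), testis proteasome (1.55, 1 of 8 higher, 0.00721, then 0.275) and general proteasome genes (1.23, 3 of 20 higher, 0.00107, then 0.393) and muscle markers (-1.01, 0 of 7 past the threshold, 0.0238, then 0.373). These hybrids share the simulans arrays as a parent.

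In the 4 mauritiana arrays, 13 of 178 tests had 1 array far from the others, where about 1 in 20 is expected by chance. Array 4 stood apart for the median of germline stem cell and spermatogonial genes (-1.07), CG13088 (3.71), CadN (1.02), Jon99Fi (-4.71), ND-B22 (1.90), RpL24-like (1.25), Rsph1 (1.88) and mei-S332 (2.74). Array 2 stood apart for CG15120 (-0.64), S-Lap7 (0.32) and comr (0.31), array 1 for the median of fat body markers (-1.56) and array 3 for wuc (0.15). No biological explanation was tested.

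Rows with no gene in the probe table also carried signal. Of 12430 such rows 5234 were tested with the same fit, and 1311 were higher and 965 lower in melanogaster testes than in whole males. These rows were tested singly and not averaged as those of named genes were. Duplicate spots thus count apart, and the counts do not compare with those of genes. In the melanogaster hybrid 506 of them lay below and 638 above both parents.

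Late germline genes lay below both parents in the melanogaster hybrid. Weaker binding of simulans RNA to probes of melanogaster sequence would place the hybrid between its parents, but late spermatid genes lay -3.47 from the lower parent, which argues against it as the whole cause. The smaller fall of the late lists exceeded the change of piRNA pathway genes, itself -0.58, by -2.04. Germline stem cell and spermatogonial genes were at 1.03 against the lower parent, simulans (medians of 0.35 in the hybrid, -0.68 in simulans and -0.32 in melanogaster). That list holds only 3 tested genes, none of them past the threshold with the spread from all arrays. A lower share of late germ cells in these testes may thus be a candidate explanation, and lower transcription in cells that are present stays open.

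Accessory gland markers lay above both parents in the melanogaster hybrid. Ratios drawn toward 0 on its arrays would raise every organ marker. Gut markers go with it, at -2.79, -2.25 and -2.59 on the hybrid arrays against -3.02 to -3.98 on the parental ones, but muscle markers moved by -1.37 from the lower parent, away from 0, which argues against it as the whole cause. Gland tissue in the samples may raise other seminal fluid genes too: the median of 6 such genes outside the list was 2.25 above the higher parent, with BG642312, Spn38F and intr past the threshold against both parents, hdly against melanogaster only, and Obp56g and Obp56e at -0.64 and -0.09. A rule written before asked for 4 of 6, so gland tissue and expression in the testis itself cannot be told apart here (the labels give no step that would remove such tissue).

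More genes passed in comparisons with sechellia than in other species pairs, but not in every fit: with the spread from the arrays compared sechellia against simulans gave 329 and mauritiana against sechellia 169, below the 1008 of mauritiana against simulans and the 925 of simulans against melanogaster. Noise independent between genes and arrays gave 96 calls in simulated arrays against 1722 in the data for the melanogaster comparison with the spread from all arrays, which argues against noise of that kind as the whole cause of this count. In the fit of the arrays compared the simulation gave 0 calls against 726, but it also recovered 0 percent of 4-fold changes, so it decides nothing. The sechellia ratios may have been prepared in another way: at least 8.01 percent of large ratios lay at the log2 of simple fractions, against at most 0.690 percent on the other arrays. A distortion shared by the 3 sechellia arrays, weaker binding of sechellia RNA to probes of melanogaster sequence and a difference of the species all stay open and untested.

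Other splits of the arrays were counted for each comparison. For mauritiana, 1 of 35 splits, the real one, gave as many genes as the real one against melanogaster (339, highest other 286), simulans (563, 506), sechellia (1166, 645) and its hybrid (230, 153). Against sechellia and against the mauritiana hybrid, where no close array pair enters, the share is under 0.05, which argues against chance. It is the smallest share that 35 splits can give and was not corrected for the number of comparisons. The sechellia arrays also differ in noise, so their split does not show a difference of the species. If melanogaster 1 and 2 and simulans 1 and 2 are repeat runs, only 15 splits exist against each of these species, too few for a share under 0.05 (averaged, the real and highest other counts were 50 and 0, and 97 and 0). In each of the 4 comparisons the highest other split moved mauritiana array 2 to the other group. With 10 splits a share under 0.05 cannot be had. There the real and highest other counts were 54 and 0 for simulans against melanogaster, 1722 and 4 for sechellia against melanogaster and 1339 and 7 against simulans. They were 1207 and 0 for the melanogaster hybrid against simulans and 1552 and 0 against melanogaster, 184 and 0 for the mauritiana hybrid against simulans, and 697 and 1 for the sechellia hybrid against simulans, each with 1 of 10 splits as large. For the sechellia hybrid against sechellia 2 of 10 splits were as large: the real one gave 583 genes and another 1581, with sechellia 2 and 3 and hybrid 2 against the rest, which points to a structure of the samples. With close array pairs averaged, another split gave 1001 genes beside the 1021 of sechellia against melanogaster, and 1133 beside the 521 against simulans. For the sechellia hybrid against sechellia 5 of 10 splits were then as large (51, highest other 1310).

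For genes outside both parents 100 splits were drawn. For the melanogaster hybrid 3 gave as many genes below (666, highest other 706) and 2 as many above (358, highest other 358). These shares are under 0.05, which argues against chance, but they were not corrected for the number of results. The others as large kept the 3 hybrid arrays together and mixed the parents. With close array pairs averaged the same numbers of 100 splits were as large (474 below, highest other 533, and 237 above, highest other 237). For the mauritiana hybrid 6 gave as many below (3, highest other 52) and 5 as many above (36, highest other 74), so chance cannot be excluded. For the sechellia hybrid 5 gave as many below (64, highest other 427) and 9 as many above (5, highest other 435), so chance cannot be excluded. The highest other splits of these 2 hybrids set other arrays apart as the tested group. The 52 and the 435 set the simulans arrays apart, the 74 mauritiana 1, 3 and 4, and the 427 sechellia 2 and 3 and hybrid 2. Such splits hold differences between species or arrays, so for these 2 hybrids they cannot decide on chance either way.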

How the results depend on the processing

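The fit without sechellia, centring on the tested genes, averaging of close array pairs and exact zeros as missing were chosen only after the data were seen. Here mel, sim, mau and sec are the species, hmel, hmau and hsec the hybrids by father, below and above mean outside both parents, and shared means outside both parents in the same direction in 2 hybrids. All 22 counts stayed within 1.5 times their value with exact zeros as missing and with a 2-fold minimum on top of the adjusted p. Without centring the counts that moved were mau-mel 211, hmau-sim 113, hmel above 197, hmau above 10, hsec below 218, hsec above 0, shared hmel/hsec 158, shared hmau/hsec 0. With arrays scaled to 1 spread the counts that moved were sim-mel 89, mau-mel 181, mau-sim 982, hmel-sim 1821, hmau-sim 592, hsec-sim 1365, hsec-sec 380, hmel above 565, hmau below 13, hmau above 58, hsec above 28, shared hmel/hmau 20, shared hmel/hsec 90, shared hmau/hsec 2. After quantile normalization the counts that moved were sim-mel 163, mau-mel 567, mau-sim 1194, hmel-sim 1954, hmau-sim 689, hsec-sim 1486, hsec-sec 373, hmel above 707, hmau below 18, hmau above 78, hsec above 76, shared hmel/hmau 27, shared hmel/hsec 90, shared hmau/hsec 5. With genes on all arrays the counts that moved were sec-sim 891, hsec-sec 337, hmau below 6, shared hmel/hmau 8, shared hmau/hsec 2. With genes on 1 array of each group the counts that moved were hmau below 1, hsec below 41, shared hmel/hmau 2, shared hmel/hsec 33, shared hmau/hsec 0. With 1 row per gene the counts that moved were hsec-sec 348, hmau below 1, hmau above 18, hsec above 9, shared hmau/hsec 0. With the spread from the arrays compared the counts that moved were sim-mel 925, mau-mel 623, sec-mel 726, mau-sim 1008, sec-sim 329, mau-sec 169, hmel-sim 2339, hmel-mel 2668, hmau-sim 513, hsec-sec 0, hmel below 1082, hmel above 865, hmau below 8, hmau above 60, hsec below 0, hsec above 0. With array weights the counts that moved were mel testes 4244, sim-mel 2997, mau-mel 1781, mau-sim 1924, sec-sim 2358, hmel-sim 2745, hmel-mel 3144, hmau-sim 2246, hmau-mau 958, hsec-sim 2088, hsec-sec 1507, hmel below 1317, hmel above 902, hmau below 81, hmau above 407, hsec below 422, hsec above 153, shared hmel/hmau 163, shared hmel/hsec 399, shared hmau/hsec 23. Without the sechellia arrays the counts that moved were sim-mel 185, mau-mel 824, mau-sim 1110, hmau-sim 460, hmau-mau 476, hsec-sim 1089, hmau below 16, hmau above 76. Centred on the tested genes the counts that moved were hmau below 7, hsec above 9, shared hmel/hmau 9, shared hmau/hsec 2. With close array pairs averaged the counts that moved were sim-mel 1, mau-mel 50, sec-mel 1021, mau-sim 97, sec-sim 521, hmau-sim 7, hmau-mau 131, hsec-sim 59, hsec-sec 51, hmel above 237, hmau below 0, hmau above 2, hsec below 0, hsec above 0, shared hmel/hmau 1, shared hmel/hsec 0, shared hmau/hsec 0. The causes were not tested, except that fewer genes or arrays enter some fits and that averaging leaves fewer arrays.

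With each array left out in turn the ranges were mel testes 1617 to 1825, sim-mel 8 to 48, mau-mel 86 to 499, sec-mel 1162 to 2090, hmel-mel 1215 to 1374, hmel below 521 to 636, hmel above 232 to 305, shared hmel/hmau 1 to 11, shared hmel/hsec 12 to 169, mau-sim 191 to 765, sec-sim 696 to 1954, hmel-sim 879 to 1029, hmau-sim 12 to 283, hsec-sim 244 to 661, hmau below 0 to 5, hmau above 1 to 71, hsec below 13 to 205, hsec above 0 to 49, shared hmau/hsec 0 to 4, mau-sec 745 to 1535, hmau-mau 101 to 296, hsec-sec 140 to 1609. The counts of mel testes, sec-mel, hmel-sim, hmel-mel and hmel below stayed within 1.5 times their value in each of these fits.

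Replicate numbers were also used as a block for pairing: mau-sim 361 and mau-sec 777 moved. The majority turned for mau-sim, with 172 higher and 189 lower against 344 and 219, and for mau-mel the split became 64 higher and 294 lower against 112 and 227. Only mauritiana had a replicate 4, so the block fits that array exactly and in effect leaves it out. Without mauritiana 4 and with no block, mau-sim had 170 higher and 161 lower, mau-mel 66 and 277, and mau-sec 745 genes. Residuals of arrays with the same number correlated at a mean r of 0.02, with single pairs from -0.33 to 0.37 and 20 of 63 above 0.1. Those with other numbers had a mean of -0.01, which follows from the first mean, since residuals of a group sum to about 0. No pairing by number was thus seen on average, but a pairing of some groups is not excluded.

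Of 616 gene values named in comparisons, 6 reversed under the scalings and 1 with 1 row per gene, and the cause was not tested. With scaled arrays Jon66Cii sec-sim became 0.83. After quantile normalization Jon66Cii sec-mel became 0.84 and sec-sim 1.59, Acp53Ea sec-sim 0.65, Jon65Aiv sec-sim 1.33 and mau-sec -0.074. With 1 row per gene apolpp in mel testes became 0.047. Of 208 list results 208 held with centring on the tested genes. This centring shifts all genes of an array alike and the lists are tested against all other genes, so it could move them little. With an estimated correlation 33 lost their call. With scaled arrays the accessory gland list sim-mel became 0.25 with a test toward lower, the gut list sim-mel -1.55 and mau-sim 1.60. After quantile normalization the gut list became 1.72 for sec-sim, -1.01 for mau-sec and -1.04 for hsec-sec. Of the gene values 119 lost their call with close array pairs averaged and 94 with the spread from the arrays compared.

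The median log2 difference of all tested genes moved by over 0.1 with the scaling: mel testes 0.18 (0.03 uncentred, -0.03 tested genes), sim-mel -0.06 (0.10 tested genes), mau-mel -0.19 (-0.04 tested genes), sec-mel -0.48 (-0.21 uncentred, -0.19 quantile, -0.15 tested genes), sec-sim -0.36 (-0.08 uncentred, -0.09 quantile, -0.19 tested genes), mau-sec 0.36 (0.11 uncentred, 0.02 quantile, 0.19 tested genes), hmel-sim 0.02 (-0.18 uncentred), hmel-mel 0.04 (-0.17 uncentred, 0.15 quantile, 0.24 tested genes), hmau-sim 0.04 (-0.22 uncentred), hmau-mau 0.15 (-0.13 uncentred), hsec-sim -0.10 (-0.39 uncentred, 0.04 quantile), hsec-sec 0.14 (-0.42 uncentred). The planned test of X-linked genes was not run, since no chromosome table was used here. Signal over background was not analysed here, and the number of arrays limits the precision.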

Other observations

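Lists with fewer than 5 tested genes were not tested as lists, and no Y-linked gene had enough values for a test. Of 4 spermatocyte transcription regulators 3 were higher in melanogaster testes (median 1.87), and 1 fell in the melanogaster hybrid against the mean of its parents (median -0.87), beside medians of -0.08 and -0.85 in the mauritiana and sechellia hybrids. Of 4 axonemal genes 3 were higher in melanogaster testes, and 1 fell in the melanogaster hybrid (median -0.74). Germline stem cell and spermatogonial genes had medians of 0.79, -0.01 and 0.17 in the melanogaster, mauritiana and sechellia hybrids, and -0.20 in melanogaster testes. Of 3 fat body markers 1 rose in the melanogaster hybrid (median -0.05), with 1 lower in melanogaster testes than in whole males. The 2 testis somatic genes and the 2 immune genes tested had medians of -0.16 and 0.10 in the melanogaster hybrid, and the 3 tested incompatibility genes 0.06. Blood cell markers had a median of 1.46 in that hybrid and -0.31 in melanogaster testes.

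In the melanogaster hybrid, gut markers (median 0.25, 1 of 10 higher, adjusted p = 0.341) and heat shock genes (median -0.47, adjusted p = 0.734) did not pass as lists (limma). In melanogaster testes, general proteasome genes had a median of 0.22 (adjusted p = 0.535), meiosis genes 0.37 (adjusted p = 0.184) and piRNA pathway genes 0.83 (adjusted p = 0.186). Oxidative phosphorylation genes had a median of -0.83 there (adjusted p = 0.0702).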
